A study of Homo sapiens with 6 samples.

How the data were processed

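RNA from RPMI-8402, a human T cell acute lymphoblastic leukaemia (T-ALL) line that carried Cas9, was sequenced in 6 samples: 3 given DMSO, the solvent control, and 3 given doxycycline for 72 hours to switch on guide RNAs against MYC. Total RNA was extracted with Qiazol and a miRNeasy kit, and strand-specific libraries were read from both ends on a DNBSEQ instrument, per the labels' protocols. The dose of doxycycline, the guide sequences and any step that removed ribosomal RNA or picked polyadenylated RNA were not given in the sources used here. The labels name no sample that received doxycycline without guides, and nothing in them says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

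Both kinds of deposited values that the series holds were used. The first was a table of raw read counts per gene, which the authors deposited without normalization; STAR 2.5.2a, featureCounts, DESeq2 1.12.4 and the hg19 build are named per the submitters' processing notes, which do not give their roles. The annotation and the strand setting of the counting were not given in the sources used here, so overlapping genes, antisense genes and near-identical copies are treated as uncertain. The other was the authors' deposited table of their DESeq2 comparison, with a mean normalized signal, a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted p-value per gene. Its settings were not given in the sources used here.

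Gene counts summed to between 23121255 and 26214598 per sample over 63677 genes. Genes with enough counts were kept with filterByExpr at its defaults, which left 15492 genes and at least 99.88% of the counts of each sample. Libraries were scaled with TMM, and the groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with treatment as the sole term. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are doxycycline over DMSO. Their standard errors (SE) were taken as the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM, a gene's share of a library's counts, with TMM scaling, as mean ± SD over 3 samples. Simulated counts had the libraries' own depths and 200 changed genes, drawn from genes with mean log2 CPM above 2. Run on 14686 genes, the test called 78% of 1.25-fold and 96% of 1.5-fold changes in the right direction. It called 100% of 2-fold and of 3-fold changes in the right direction, with 12 calls among unchanged genes. The shares of changes called do not cover genes at lower levels.

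A set of 33 gene lists was written from general knowledge before the data were examined, as were the tests, their alternatives and the rule for genes named in the text. Of these lists, 29 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. Camera asks whether a list's genes differ from all other genes. An estimated correlation per list, and fry, which asks whether a list's own genes move on balance in 1 direction, were further tests fixed at that time. The text names MYC; the 8 largest rises and 8 largest falls among called genes with mean log2 CPM of at least 3, a gene symbol that is not a clone name and no overlap between groups; the 3 members of each tested list with the smallest p, or 2 for marker lists of other cell types; and every called member of the MYC network, the CDK inhibitors and D cyclins, and the BCL2 family. Where a list had 5 or fewer calls in a direction, further members are named that were chosen after their values were seen. Some genes that these rules select are not reported here.

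Because fold changes followed the GC content of genes, a correction was added after the data were examined. The GC content and length of each gene's longest transcript were taken from GENCODE 29, matched by gene identifier for 97.1% of tested genes. That annotation is of GRCh38 rather than hg19, so no coordinates are given. Per library, the deviation of log2 CPM (prior count 2, genes with mean log2 CPM above 2) from the gene's mean was fitted with natural splines of GC content and of log2 length, each with 5 degrees of freedom, and the fitted trend entered the edgeR model as an offset for 15036 genes. The correction removes any true change that follows GC content or length along with a technical trend. When a GC trend was added to simulated counts of 14680 genes, calls among unchanged genes numbered 395 without the correction and 11 with it. That trend was linear in the same GC values that the correction fits, and no length trend was added. The simulation therefore does not show how well the trend in the real libraries is removed. Each list's median was also placed among 10000 random lists matched gene by gene on GC content, length and expression in 10, 5 and 5 bins. The correction covered 8 of 12 tested histone genes, too few for that check to hold for the histone list.

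Other alternatives were DESeq2 size factors, upper-quartile scaling or library size alone, no filter or a CPM of at least 1 in 3 samples, the replicate number as a block, leaving out each sample, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, and glmTreat with a fold of 1.5. Leaving out DMSO replicate 2 and doxycycline replicate 1 together was added after the data were examined. Replicates differed by more than sampling noise, with a chi-square per gene of 2.74 to 7.13 over genes with at least 20 counts in a pair. All 6 samples were therefore kept as separate libraries. Differences in library preparation could also give such an excess, so it does not show separate cultures. Transcripts of nuclear copies of mitochondrial genes with at least 60 counts were aligned to mitochondrial transcripts with blastn 2.17.0.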

Results

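The series profiled gene expression in RPMI-8402 cells, a T-ALL line, to ask what follows when Cas9 is directed at MYC, the transcription factor that drives growth in many T cell leukaemias. Counts per gene were available for 3 DMSO samples and 3 doxycycline samples taken at 72 hours. Total counts were 25412493, 24957795 and 23121255 in DMSO replicates 1, 2 and 3, and 26199815, 25819386 and 26214598 in doxycycline replicates 1, 2 and 3. Group names follow the labels.

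The count of MYC (ENSG00000136997) was not lower in the doxycycline samples. MYC stood at 409, 422 and 407 CPM in DMSO replicates 1, 2 and 3, and at 459, 431 and 431 CPM in doxycycline replicates 1, 2 and 3. Means were 413 ± 8.01 CPM in DMSO and 440 ± 16.0 CPM in doxycycline (SD, n = 3 each), a log2 fold change of 0.09 with an SE of 0.049 (edgeR adjusted p = 0.160). With upper-quartile scaling MYC passed the test as higher, at 0.14 (edgeR adjusted p = 0.0357), and with library size alone at 0.14 (edgeR adjusted p = 0.0281), within a range of 0.0281 to 0.441 over its alternatives. Small insertions or deletions at a cut site leave most reads of a gene countable, so a gene-level count tests the labels only in part.

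In the doxycycline samples, many genes that build ribosomes, fold proteins, make nucleotides and serve mitochondria fell, among them 34 of 46 of nucleolar ribosome assembly, 18 of 22 chaperones and 20 of 25 of nucleotide synthesis. Of 30 genes of thymocyte and T cell identity 8 rose, KLF2 among them, and 1 fell. As lists these passed camera at its preset correlation, as did 19 of 29 lists, and 0 of 29 passed with an estimated correlation (9 at unadjusted p under 0.05; fry called 23). NOTCH3, a receptor of the NOTCH family, went from 35.1 ± 2.39 to 68.8 ± 2.11 CPM, and NME1, a nucleoside diphosphate kinase, from 149.5 ± 16.0 to 91.0 ± 0.656 CPM (SD, n = 3 each). Most changes were small, with a median size of 0.27 on the log2 scale among changed genes. In all, 4545 of 15492 genes changed, 2137 higher and 2408 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Changes of at least 1.5-fold were found for 605 of them, 551 higher and 54 lower, and of at least 2-fold for 211, 188 higher and 23 lower. Genes with any counts numbered 23297, 23188 and 23310 in DMSO replicates 1, 2 and 3. In doxycycline replicates 1, 2 and 3, where total counts were also higher, they numbered 23932, 24519 and 24573. Whether low-count genes rose as a class was not tested, so large rises at low levels may not be particular to the genes named.

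The groups did not overlap for 6465 tested genes, or 41.7%, where chance gives 10%. The share of changed genes that were higher was 47.0%, against 64.4% with upper-quartile scaling (2871 higher, 1585 lower) and 63.2% with library size alone (2758 higher, 1606 lower). Upper-quartile scaling also moved list medians by over 1.5-fold with no change of call: RNA polymerases I and III to -0.07, ribosomal proteins to -0.07, tRNA synthetases to -0.08, mitosis to -0.06, polyamines to -0.06, cholesterol synthesis to -0.03, the MYC network to 0.12, CDK inhibitors and D cyclins to 0.08, p53 targets to 0.12, the BCL2 family to 0.06, the TAL1 circuit to 0.13 and HLA genes to 0.11. With library size alone these medians were close to those values. With GC content and length corrected, 3310 of 15036 genes changed, 1601 higher and 1709 lower, of which 2293 were also called without the correction and 2285 of these in the same direction. In the authors' deposited table, 3498 genes had an adjusted p-value under 0.05, 1348 higher and 2150 lower, and 3434 of them were called by edgeR too, all 3434 in the same direction. The authors' deposited table gives MYC a log2 fold change of 0.08 with a standard error of 0.044 (DESeq2 adjusted p = 0.170).

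**Figure D1:**
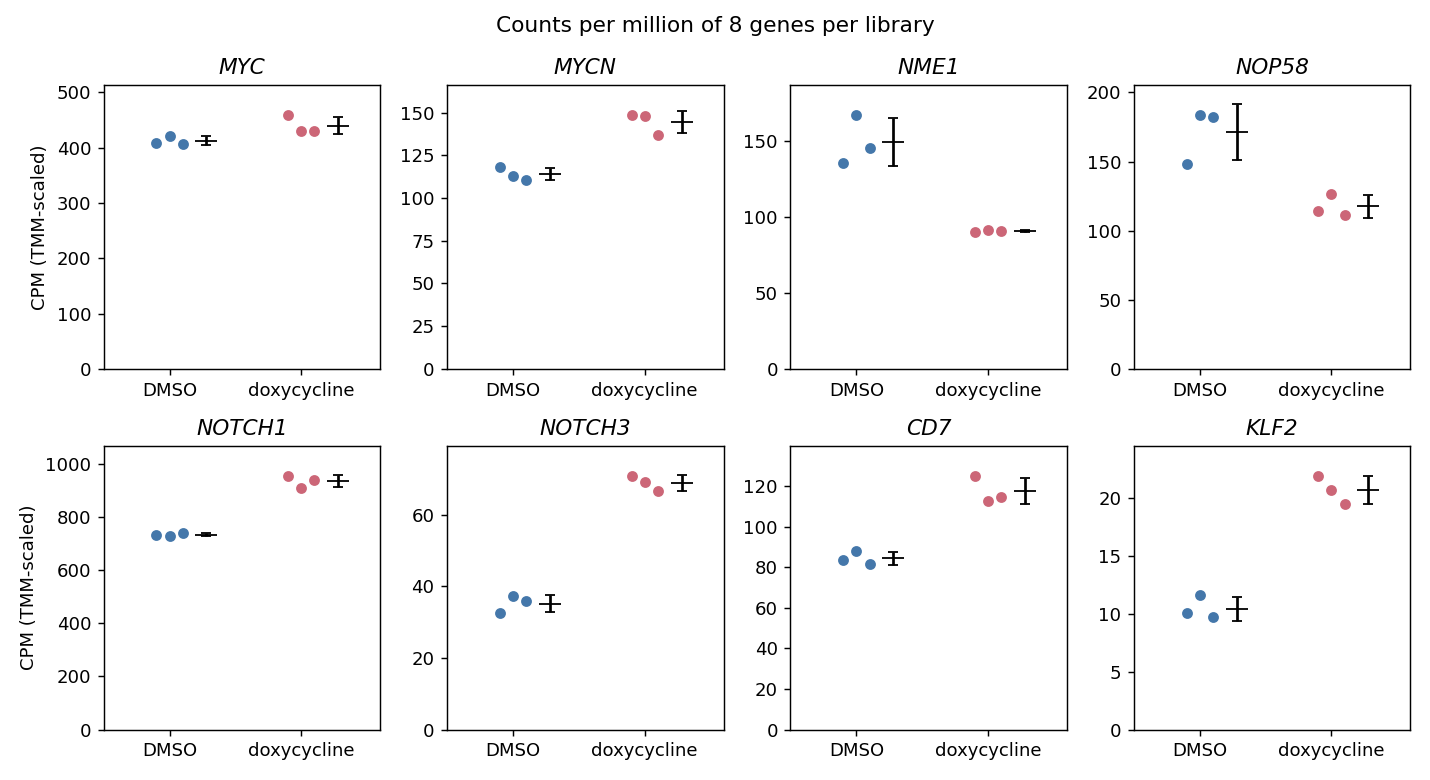
CPM (y axis, TMM-scaled, from 0) of 8 genes in each DMSO (blue) and doxycycline (red) library; points are libraries and the black marks are the mean with 1 SD of 3 libraries. MYC lies at 407 to 422 CPM in DMSO and 431 to 459 CPM in doxycycline, NME1 and NOP58 are lower in all 3 doxycycline libraries, and the other 5 genes are higher in all 3.

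Among the largest rises were those of SH2D2A, a T cell adaptor protein, at 1.40 on the log2 scale, the keratin gene KRT72 at 1.33, the microRNA host MIR663A at 1.31, KLF2 at 0.99, MYO15B at 0.99, the integrin gene ITGAL at 0.97 and NOTCH3 at 0.97 (SE 0.060). SH2D2A went from 5.66 ± 0.439 to 14.9 ± 1.43 CPM and KLF2 from 10.4 ± 1.02 to 20.7 ± 1.20 CPM (SD, n = 3 each). Among the largest falls, the gene named hsa-mir-6723 in the authors' deposited table, which GENCODE 29 names MTCO1P12, a nuclear copy of a mitochondrial gene, fell by 0.82. NME1 fell by 0.72 (SE 0.060), USMG5, a subunit of ATP synthase, by 0.65, the histone pseudogene H3F3AP4 by 0.64, CCDC59 by 0.63, the aspartyl-tRNA synthetase DARS by 0.61, the ubiquitin ligase subunit RBX1 by 0.60 and PRTFDC1 by 0.60. Across these 15 genes the edgeR adjusted p ran from 2.20e-11 for NOTCH3 to 1.52e-05 for H3F3AP4, and all 15 were called in the same direction with GC content and length corrected, where CCDC59 and PRTFDC1 each fell by 0.38. Counts of hsa-mir-6723 and H3F3AP4 are uncertain because each has near-identical copies, and NME1 overlaps the read-through gene NME1-NME2.

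Of 46 tested genes of ribosome assembly in the nucleolus, 34 fell and 0 rose by edgeR (37 fell adjusted over the list alone), with a median log2 fold change of -0.23 (camera adjusted p = 3.21e-16, and adjusted p = 0.110 with an estimated correlation). NOP58, a core protein of the box C/D particles that guide ribosomal RNA methylation, fell by 0.54 (SE 0.066) from 171 ± 20.2 to 118 ± 8.15 CPM, LYAR by 0.42 and the helicase DDX21 by 0.38 (SD, n = 3 each). With GC content and length corrected, 38 of 45 fell and the median was -0.22, and NOP58 and LYAR fell by 0.36 and 0.23. Of 32 subunits and factors of RNA polymerases I and III, which transcribe ribosomal and transfer RNA, 13 fell and 3 rose (15 and 3 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 4.70e-04, and adjusted p = 0.110 with an estimated correlation). CD3EAP and TWISTNB, both subunits of RNA polymerase I, fell by 0.78 and 0.43, and POLR3G, of RNA polymerase III, by 0.52. TAF1C, BRF1 and GTF3C1 rose by 0.25, 0.18 and 0.15. After the correction 11 fell and 0 rose, with a median of -0.09, and TWISTNB and POLR3G fell by 0.27 and 0.32.

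Of 35 translation initiation factors, 19 fell and 0 rose (21 fell adjusted over the list alone), with a median of -0.15 (camera adjusted p = 1.62e-09, and adjusted p = 0.136 with an estimated correlation). EIF1AX fell by 0.52, EIF5A by 0.36 from 715 ± 36.2 to 557 ± 10.6 CPM, and EIF2S2 by 0.35 (SD, n = 3 each). Of 20 cytosolic tRNA synthetases, which load amino acids onto transfer RNA, 11 fell (12 adjusted over the list alone), among them DARS by 0.61, GARS by 0.41 and FARSB by 0.34, with a list median of -0.13 (camera adjusted p = 8.67e-06, and adjusted p = 0.254 with an estimated correlation), at percentile 12.01 of random lists matched on GC content, length and expression. Of 22 protein folding chaperones, 18 fell (19 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 2.68e-12, and adjusted p = 0.169 with an estimated correlation). HSPD1, the mitochondrial chaperonin, fell by 0.38, and CCT2 and CCT8, subunits of the cytosolic chaperonin, by 0.36 and 0.32. With GC content and length corrected, 15 initiation factors, 10 tRNA synthetases and 16 chaperones fell and 1 initiation factor, EIF3F, rose, with medians of -0.12, -0.10 and -0.15. FARSB, HSPD1 and CCT8 then fell by 0.20, 0.25 and 0.15, and RPS13, of the list below, by 0.17. Of 50 cytosolic ribosomal proteins, 20 fell, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 2.36e-05, and adjusted p = 0.445 with an estimated correlation). RPL34 fell by 0.44, RPS13 by 0.28 and RPL14 by 0.24. Genes of this list have many near-identical pseudogenes, so their counts are uncertain. The ribosomal protein median was -0.06 without DMSO replicate 2 and -0.05 with the correction, lay at percentile 64.2 of such matched lists, and had a fry adjusted p = 0.148. With the correction 12 of the 50 fell and 0 rose.

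Of 38 proteins of the mitochondrial ribosome, 29 fell and 0 rose (35 fell adjusted over the list alone), with a median of -0.25 (camera adjusted p = 2.71e-13, and adjusted p = 0.136 with an estimated correlation). MRPL1 fell by 0.54, MRPS23 by 0.49 from 27.7 ± 1.78 to 19.7 ± 1.47 CPM and MRPS35 by 0.37 (SD, n = 3 each). Of 45 nuclear subunits of oxidative phosphorylation, 32 fell and 0 rose (36 fell adjusted over the list alone), with a median of -0.21 (camera adjusted p = 1.94e-12, and adjusted p = 0.225 with an estimated correlation). COX7B of complex IV fell by 0.43, SDHD of complex II by 0.41 and ATP5C1 of ATP synthase by 0.30. After the GC and length correction 15 mitochondrial ribosome genes and 21 respiratory genes fell, with medians of -0.14 and -0.13, 1 respiratory gene, COX6C, rose, and ATP5C1 no longer passed (-0.08, edgeR adjusted p = 0.167). MRPL1, MRPS35, COX7B and SDHD then fell by 0.29, 0.17, 0.27 and 0.18. The 13 protein-coding genes of the mitochondrial genome had 0 counts in every sample and were not tested.

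Of 25 tested genes of purine and pyrimidine synthesis, 20 fell and 0 rose, also adjusted over the list alone, with a median of -0.20 (camera adjusted p = 1.13e-08, and adjusted p = 0.110 with an estimated correlation). Besides NME1, PAICS fell by 0.40 from 726 ± 40.7 to 549 ± 24.6 CPM, and RRM1, the large subunit of ribonucleotide reductase, by 0.27 (SD, n = 3 each). Of 19 genes of serine and 1-carbon metabolism, 11 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 5.90e-04, and adjusted p = 0.136 with an estimated correlation). PSAT1 fell by 0.32, SLC25A32 by 0.40 and MTHFD1L by 0.37, while AMT rose by 0.34. With the correction 15 genes of nucleotide synthesis fell and 1, IMPDH2, rose, and 9 of serine and 1-carbon metabolism fell and 0 rose, with medians of -0.14 and -0.13. RRM1, PSAT1 and SLC25A32 then fell by 0.15, 0.15 and 0.23. Of 22 glycolysis genes, 10 fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0279, and adjusted p = 0.345 with an estimated correlation). PGAM1 fell by 0.37 and LDHA, which makes lactate, by 0.31, whereas the aldolase ALDOC rose by 0.89 and the transporters SLC2A3 and SLC16A3 by 0.61 and 1.01, SLC16A3 at under 1 CPM and not with the correction. The glycolysis call was lost without DMSO replicate 2 (camera adjusted p = 0.0719), without doxycycline replicate 2 (0.0582) or 3 (0.0716), with upper-quartile scaling (0.0662) and with library size alone (0.0535). It held with GC content and length corrected, at a median of -0.15, and LDHA then fell by 0.17.

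Of 11 genes of polyamine metabolism, 5 fell and 1 rose, also adjusted over the list alone, and the list did not pass (median -0.10, camera adjusted p = 0.0531). ODC1 and AMD1, which commit ornithine and S-adenosylmethionine to polyamines, fell by 0.28 and 0.35, as did SMS by 0.24 (with the correction -0.10, edgeR adjusted p = 0.0556), SRM by 0.22 and AZIN1 by 0.20, and SAT1, which acetylates polyamines for removal, rose by 0.38. The polyamine list passed without DMSO replicate 1 (camera adjusted p = 0.0370), DMSO replicate 3 (0.0261) or doxycycline replicate 1 (0.0264), with no filter on low counts (0.00340) and with the correction (0.0161). Its median was -0.06 without DMSO replicate 2 and -0.17 without doxycycline replicate 1. Fry called it as lower (adjusted p = 0.0131). With the correction AMD1 and AZIN1 fell by 0.21 and 0.11, SQLE of cholesterol synthesis fell by 0.14, and SAT1 rose by 0.60. Of 23 genes of cholesterol synthesis, 8 fell and 2 rose, also adjusted over the list alone, and the list did not pass (median -0.08, camera adjusted p = 0.0954; 0.0428 with the correction, 0.00613 with no filter and 0.0210 by fry). TM7SF2 and MVD rose by 0.47 and 0.23, MVD not with the correction (0.10, edgeR adjusted p = 0.214), and INSIG1 and SQLE fell by 0.25 and 0.22. Of 13 amino acid transporters, SLC38A5 fell by 0.34, SLC38A1 by 0.18 and SLC6A6 rose by 0.17, also adjusted over the list alone, and the list did not pass (median -0.03, 0.02 with upper-quartile scaling, 0.01 with library size alone, 0.01 without DMSO replicate 3 and 0.00 without doxycycline replicate 3; camera adjusted p = 0.394, and 0.0230 with the correction). With the correction the transporter median was -0.107, and 5 fell and 0 rose. The SLC38A1 call was lost without DMSO replicate 1 (edgeR adjusted p = 0.0982) or doxycycline replicate 1 (0.165), where its change was -0.12, and with upper-quartile scaling (0.0767) or library size alone (0.0886). That of SLC6A6 was lost without DMSO replicate 1 (0.109), DMSO replicate 2 (0.0804), doxycycline replicate 1 (0.0506) or doxycycline replicate 3 (0.130), with DMSO replicate 2 and doxycycline replicate 1 both left out (0.103), with no filter (0.0595) and with the correction (0.177).

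Of 35 DNA replication genes, 18 fell and 4 rose (21 and 4 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 1.71e-04, and adjusted p = 0.281 with an estimated correlation). RFC3 fell by 0.40, GINS1 by 0.35 and PCNA, the sliding clamp, by 0.27, while E2F2, CDT1, MCM5 and POLE rose by 0.17, 0.18, 0.15 and 0.14. With the correction 10 fell and 0 rose, with a median of -0.10, RFC3 and GINS1 fell by 0.20 and 0.21, and PCNA did not pass (-0.09, edgeR adjusted p = 0.114). Of 34 mitosis genes, 16 fell and 1, CDC25B, rose (17 and 1 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 4.05e-04, and adjusted p = 0.281 with an estimated correlation). MAD2L1 fell by 0.35, CKS2 by 0.26 and the spindle motor KIF11 by 0.22. After the correction 1 mitosis gene fell and 1 rose, CDC25B did not pass (0.09, edgeR adjusted p = 0.110), the median was -0.01 (camera adjusted p = 0.503; percentile 91.8 of matched random lists without the correction), and neither CKS2 (0.00, edgeR adjusted p = 0.957) nor KIF11 (-0.09, 0.113) passed. Of 13 CDK inhibitors, D cyclins and partners, 2 rose and 2 fell, also adjusted over the list alone, and the list did not pass (median 0.03, camera adjusted p = 0.333; 0.0462 with the correction). That median was 0.02 without DMSO replicate 1, 0.02 without DMSO replicate 2, 0.00 without DMSO replicate 3 and 0.00 without doxycycline replicate 2. With the correction it was 0.086. CDKN1A, the inhibitor p21, rose by 1.67 from 0.460 ± 0.105 to 1.46 ± 0.242 CPM and CCND2 by 1.66 from 0.307 ± 0.118 to 0.970 ± 0.188 CPM, both near the lowest levels tested (SD, n = 3 each). CDK4 fell by 0.21 from 112 ± 11.4 to 96.6 ± 1.69 CPM, and was not called when DMSO replicate 2 and doxycycline replicate 1 were both left out (edgeR adjusted p = 0.0668). CCNG1 fell by 0.15 (edgeR adjusted p = 0.0424), a call lost without DMSO replicate 1 (0.117), DMSO replicate 3 (0.181), doxycycline replicate 1 (0.203) or doxycycline replicate 3 (0.107), with upper-quartile scaling (0.166), library size alone (0.174) or the stricter filter (0.0568), and its sign turned with the correction (0.04).

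Within the MYC network itself, 4 of 12 tested genes rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0140, and adjusted p = 0.156 with an estimated correlation). MYCN, the paralog of MYC, rose by 0.34 (SE 0.051) from 114 ± 3.65 to 144 ± 6.43 CPM, and MXD4 and MNT, which compete with MYC for its partner MAX, rose by 0.59 and 0.32 (SD, n = 3 each). MLXIP, a partner of MLX that responds to glucose, rose by 0.20, and MLX fell by 0.14 (edgeR adjusted p = 0.0433). The MLX call was lost without DMSO replicate 1 (0.0983), DMSO replicate 2 (0.115), doxycycline replicate 2 (0.135) or doxycycline replicate 3 (0.179), with upper-quartile scaling (0.194), library size alone (0.157) or the stricter filter (0.0565). The network's median lay at percentile 79.3 of matched random lists, and was 0.11 without DMSO replicate 2. With GC content and length corrected the list did not pass (median 0.04, camera adjusted p = 0.142). MYCN and MXD4 rose by 0.28 and 0.47, MNT did not pass (0.13, edgeR adjusted p = 0.0749), and the sign of MLXIP turned (-0.01, edgeR adjusted p = 0.895).

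Of 30 tested genes of thymocyte and T cell identity, 8 rose and 1 fell, also adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.00100, and adjusted p = 0.110 with an estimated correlation). KLF2, a regulator of T cell trafficking and quiescence, rose by 0.99, the surface protein CD7 by 0.48 from 84.5 ± 3.23 to 118 ± 6.51 CPM and the chemokine receptor CCR9 by 0.51, and CD3G fell by 0.24 (SD, n = 3 each). With the correction 10 rose and 0 fell, with a median of 0.10, and CD3G did not pass (-0.07, edgeR adjusted p = 0.234). Of 15 NOTCH receptors and targets, 6 rose and 1, SHQ1, fell (7 and 1 adjusted over the list alone), with a median of 0.12 (0.08 without DMSO replicate 1; camera adjusted p = 6.20e-04, and adjusted p = 0.110 with an estimated correlation). That median lay at percentile 89.99 of random lists matched on GC content, length and expression. Besides NOTCH3, NOTCH1 rose by 0.35 (SE 0.049) from 733 ± 5.60 to 934 ± 22.0 CPM and DTX1 by 0.36. After the GC and length correction 5 rose and 0 fell, the median was 0.01 (camera adjusted p = 0.0294), NOTCH3 rose by 0.69, DTX1 by 0.20, and NOTCH1 did not pass (0.06, edgeR adjusted p = 0.252). Of 15 genes of the TAL1 circuit, a transcription factor group active in T-ALL, 5 rose and 1 fell, also adjusted over the list alone, and the list did not pass (median 0.08, camera adjusted p = 0.155; fry called it as higher, adjusted p = 0.0160). RUNX1 rose by 0.19, ARID5B by 0.22, HHEX by 0.15, LDB1 by 0.15 and GATA3 by 0.15. With the correction LDB1 (0.07, edgeR adjusted p = 0.257) and GATA3 (0.11, 0.0634) did not pass, and HHEX rose by 0.29. ARID5B was not called when DMSO replicate 2 and doxycycline replicate 1 were both left out (edgeR adjusted p = 0.0819).

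Of 29 interferon response genes, 7 rose and 0 fell, also adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.0124, and adjusted p = 0.281 with an estimated correlation). ISG20 rose by 0.59, IRF7 by 0.42 and IRF9 by 0.67. The interferon median was 0.17 without DMSO replicate 2, 0.07 without DMSO replicate 3 and 0.17 with the correction, where 11 rose and IRF7 rose by 0.28. Of 33 lysosome and autophagy genes, 9 rose and 3 fell (11 and 4 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0289, and adjusted p = 0.359 with an estimated correlation). ULK1, the kinase that starts autophagy, rose by 0.30, the glucosidase GAA by 0.26 and the sialidase NEU1 by 0.29, and ATG9B, GABARAPL2 and GLA fell by 0.29, 0.20 and 0.21. The lysosome call was lost without DMSO replicate 1 (median 0.07, camera adjusted p = 0.0553), DMSO replicate 3 (0.0629) or doxycycline replicate 1 (0.0703), and with the correction (median 0.06, 0.0997), where ULK1 (0.08, edgeR adjusted p = 0.153), GAA (0.08, 0.175), GABARAPL2 (-0.03, 0.721) and GLA (-0.09, 0.346) did not pass and ATG9B fell by 0.48. Of 12 tested histone genes of the replication-dependent kind, none above 9.6 CPM in any sample, 4 rose and 1 fell, also adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.0155, and adjusted p = 0.281 with an estimated correlation). HIST2H2BE rose by 1.05, HIST1H2AG by 0.62, HIST1H4H by 1.01 and HIST1H2BJ by 0.54, and HIST2H2AC fell by 0.65. Without DMSO replicate 3 the histone call was lost (camera adjusted p = 0.0629). With GC content and length corrected the histone median was 0.60 over the 8 genes that could be corrected (camera adjusted p = 0.00128), too few of the 12 for that check to hold.

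For stress, survival and antigen presentation the lists did not pass. Of 21 p53 target genes, 7 rose and 2 fell, also adjusted over the list alone (median 0.08, 0.04 without DMSO replicate 1 and 0.13 without DMSO replicate 2; camera adjusted p = 0.0905, 0.0259 with the correction and 0.00357 by fry). TP53INP1 rose by 0.55 and PHLDA3 by 1.04, and TRIAP1 and GADD45A fell by 0.31 and 0.29. TRIAP1 did not pass with the correction (-0.10, edgeR adjusted p = 0.277). Among 16 genes of the integrated stress response, DDIT4, PPP1R15A, SESN2 and CEBPB rose by 0.59, 0.35, 0.26 and 0.21, and XPOT and ATF5 fell by 0.26 and 0.27 (5 higher and 2 lower adjusted over the list alone; median 0.12, 0.08 without DMSO replicate 3, 0.07 without doxycycline replicate 2 and 0.07 with the correction; camera adjusted p = 0.163). With the correction 4 genes of this list rose and 2 fell, but the genes that rose were not all the same. SESN2 (0.14, edgeR adjusted p = 0.0923) and CEBPB (0.07, 0.334) then did not pass, and other members did. Of 12 BCL2 family genes, the death promoter BMF rose by 0.45 from 22.8 ± 0.885 to 31.0 ± 1.68 CPM and BID fell by 0.26, also adjusted over the list alone (SD, n = 3 each). The BCL2 family median was 0.01, its mean lay just below 0 (-0.003), and camera, which gave the direction as up, had an adjusted p = 0.864. Without DMSO replicate 3 the median was -0.01 and without doxycycline replicate 1 it was -0.005. It was 0.02 without DMSO replicate 2 and 0.03 without doxycycline replicate 2 or 3. PMAIP1 had a log2 fold change of -0.13 (edgeR adjusted p = 0.142). It was called without DMSO replicate 2 (-0.20, 0.0225), was -0.08 without DMSO replicate 3, and turned sign with the correction (0.10). In the HLA and antigen presentation list of 16 genes, HLA-E and NLRC5 rose by 0.23 and 0.24 and the immunoproteasome subunits PSMB9 and PSMB8 fell by 0.28 and 0.21, also adjusted over the list alone (median 0.06, 0.03 without DMSO replicate 1, 0.04 without doxycycline replicate 2 and 0.02 with the correction, where camera gave the direction as down; camera adjusted p = 0.696). NLRC5 did not pass with the correction (0.05, edgeR adjusted p = 0.604).

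Some genes of the marker lists of other blood and tissue cells were expressed, which does not show that such cells were present. Of 12 B cell markers 8 were tested, 2 rose and 0 fell, and CD79A rose by 0.96 from 3.09 ± 0.511 to 6.02 ± 1.28 CPM, also adjusted over the list alone (SD, n = 3 each; list median 0.12, 0.06 with the correction and -0.01 with no filter; camera adjusted p = 0.155, and 0.00514 by fry). The B cell markers BLK and IGLL1 were at 61.8 ± 0.467 and 20.2 ± 1.95 CPM in DMSO and 67.8 ± 3.90 and 18.8 ± 0.618 CPM in doxycycline, and did not pass (SD, n = 3 each). Of 13 myeloid markers, MPO and S100A9 were tested, and MPO rose by 1.14 to 1.35 ± 0.101 CPM. Of 14 erythroid and megakaryocyte markers, EPOR, AHSP and ITGA2B were tested, EPOR was at 22.6 ± 2.05 and 23.8 ± 1.11 CPM and did not pass, and ITGA2B rose by 0.90 to 1.48 ± 0.182 CPM. Of 14 stromal and epithelial markers, COL1A1, CDH2, VIM and VWF were tested. VIM was at 716 ± 37.7 CPM in DMSO and 684 ± 17.5 CPM in doxycycline and CDH2 at 73.5 ± 0.482 and 72.1 ± 1.49 CPM, and neither passed. COL1A1 rose by 0.31 from 40.1 ± 0.181 to 49.6 ± 2.96 CPM and VWF by 1.17 to 1.16 ± 0.217 CPM. COL1A1 did not pass with GC content and length corrected (0.08, edgeR adjusted p = 0.241). These last 3 marker lists had too few tested genes for camera.

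**Figure D2:**
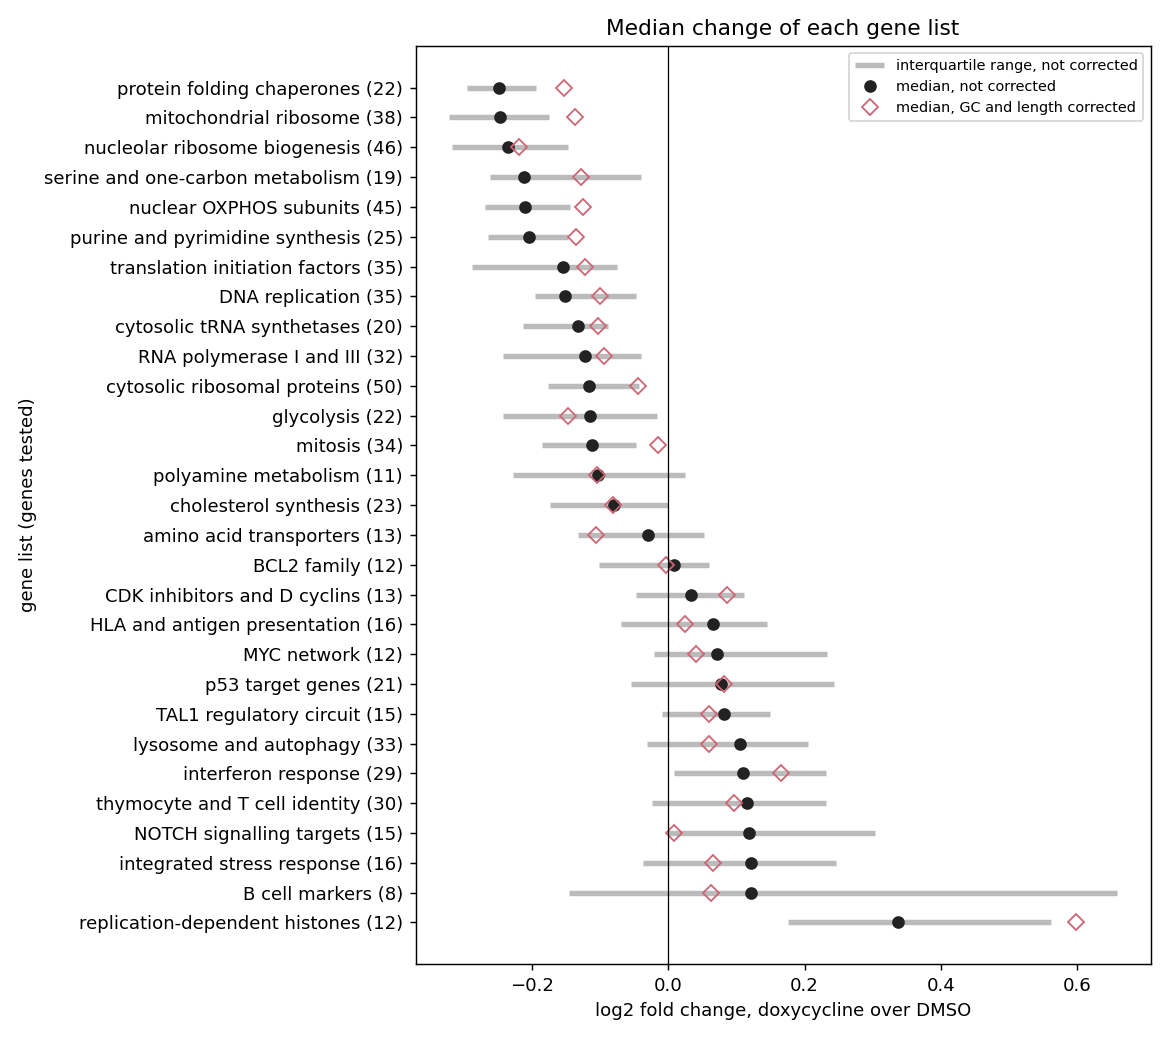
Median log2 fold change, doxycycline over DMSO (x axis), of the tested members of 29 gene lists (y axis, number of genes in parentheses), without correction (filled points, with the interquartile range of members as grey bars) and with GC content and length corrected (open diamonds). Nucleolar ribosome biogenesis lies at -0.23 without and -0.22 with the correction, and mitosis at -0.11 and -0.01; the corrected histone value covers 8 of 12 genes.

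Fold changes followed the base composition of the transcripts. Across 8061 genes with mean log2 CPM above 4, which are not independent replicates, Spearman's rho of the log2 fold change was 0.518 with GC content and 0.239 with length. The median log2 fold change was -0.16 in the 10% of genes lowest in GC content and 0.12 in the 10% highest, and -0.02 and -0.04 after the correction. The deviation of each library from the mean of all libraries had a rho with GC content of -0.61, -0.01 and -0.61 in DMSO replicates 1, 2 and 3 and 0.64, 0.25 and 0.35 in doxycycline replicates 1, 2 and 3. With length the values were -0.07, -0.53 and 0.05 in DMSO and 0.05, 0.28 and 0.31 in doxycycline, and in both measures DMSO replicate 2 and doxycycline replicate 1 lay furthest from the other samples of their group. Without these 2 libraries 3536 genes changed, 1621 higher and 1915 lower.

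**Figure D3:**
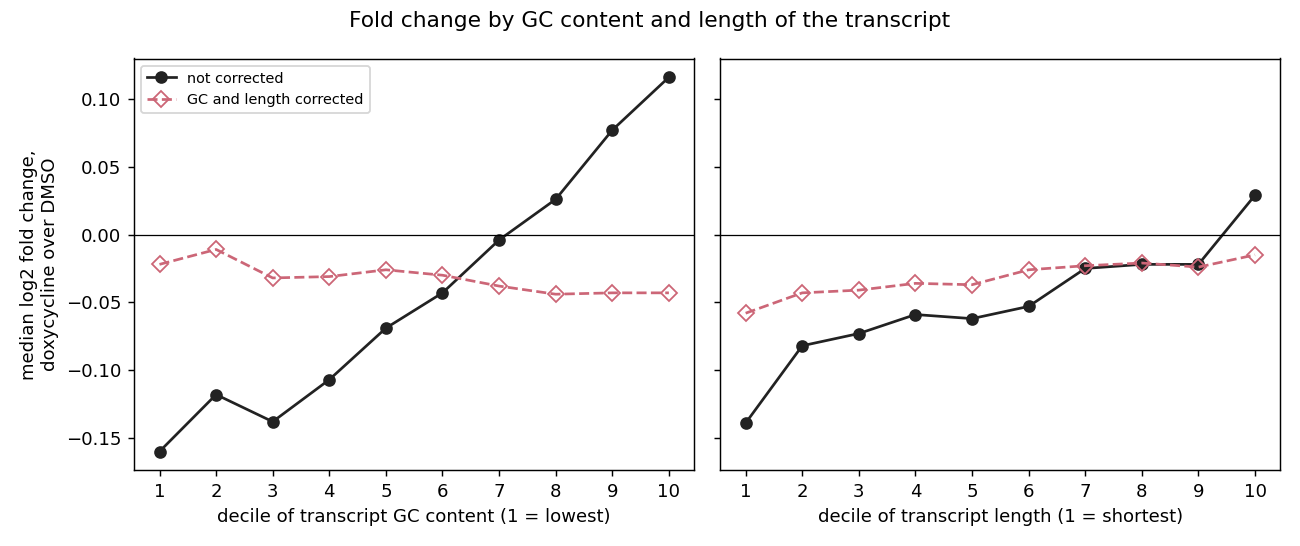
Median log2 fold change, doxycycline over DMSO (y axis), of genes in 10 equal groups by transcript GC content (left, x axis) and transcript length (right, x axis), without (filled points) and with (open diamonds) the GC and length correction. Without correction the median goes from -0.16 to 0.12 along GC content and from -0.14 to 0.03 along length.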

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

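Of 102 named-gene changes, 82 kept their direction and their side of the threshold under every alternative and 4 turned sign under some; of 29 lists 1 kept both under all. Genes changed numbered 4364 to 4532 with other scalings, 4471 and 4418 with other filters, 4515 with limma-voom, and 3396 to 4366 with 1 sample left out (2022 higher and 2344 lower without DMSO replicate 2). DESeq2, fitted here to all genes of the count table, gave 1348 higher, and its 3498 calls, 1348 higher and 2150 lower, are the same counts as in the authors' deposited table, so they are no separate check of it. Upper-quartile scaling gave 1585 lower. A change of scaling moves the log2 fold changes of all genes together. With upper-quartile scaling MYC went from 0.092 to 0.14, MLX from -0.143 to -0.095 and CCNG1 from -0.154 to -0.106. The median over all genes was -0.001 with TMM and 0.043 with library size alone. Which scaling is right was not tested, nor was the cause of the DESeq2 count. An adjusted p under 0.01 left 2701 genes, 1228 higher and 1473 lower, and glmTreat with a fold of 1.5 left 44, 42 higher and 2 lower, because both ask for more. With the GC and length correction and 1 sample left out the count went down to 2230 (doxycycline replicate 3), with as few as 1105 higher (DMSO replicate 2) and 1095 lower (doxycycline replicate 3), where fewer samples were tested. MYC was at 0.14 with upper-quartile scaling and 0.136 with library size alone. With the GC and length correction, and with the replicate block added to it, the log2 fold changes that turned were MLXIP -0.009 and -0.009, CKS2 0.004 and 0.005, CCNG1 0.043 and 0.044, PMAIP1 0.103 and 0.105, and the HLA list 0.024 and 0.023 (direction by camera); the correction's own construction takes out what follows GC content and length. The BCL2 family median went from -0.012 without DMSO replicate 3 to 0.03 without doxycycline replicate 2, was -0.005 without doxycycline replicate 1, and -0.003 with DMSO replicate 2 and doxycycline replicate 1 both left out; the cause was not tested.

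With an estimated correlation 0 lists were higher and 0 lower by camera, 9 had an unadjusted p under 0.05, and fry called 9 higher and 14 lower; with the preset correlation 6 were higher and 13 lower. No gene was in more than 1 of the lists written before the data were examined. With replicate number as a block 4206 genes changed, and the calls of MLX (edgeR adjusted p = 0.0665) and CCNG1 (0.0590) were lost; with the correction too, 3209 changed, SQLE did not pass (0.0502) and the list of CDK inhibitors and D cyclins lost the call that the correction alone gave. Among the named genes and the 29 lists it changed no other call. Residuals of samples with the same number had correlations of -0.04, -0.048 and 0.01, so no sample correlated best with its own number. By the simulation, 78% of the smallest changes tried were called at these depths, so small changes can be missed. Those changes were placed in genes with mean log2 CPM above 2, so genes at lower levels were not covered.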

Other observations

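The 5 gene lists of this part were written after values of other genes had been seen, with the genes that prompted them left out. They were adjusted over these 5 alone, so their adjusted p-values cannot be set beside those of the 29 earlier lists. With an estimated correlation, purine and pyrimidine synthesis had a camera p = 0.0101 unadjusted and 0.110 adjusted over the 29. Leaving out the prompting genes does not remove the selection, because other members of a list may move with them. None of the 5 was placed among matched random lists. Of 24 immediate early and ERK feedback genes, 12 rose and 0 fell, with a median log2 fold change of 0.41 (camera adjusted p = 1.20e-06, and adjusted p = 0.0227 with an estimated correlation). FOSL2 rose by 0.49 and JUNB by 0.44 from 34.2 ± 2.78 to 46.4 ± 2.01 CPM (SD, n = 3 each). At low levels, NR4A1 rose by 1.31 from 1.19 ± 0.188 to 2.95 ± 0.506 CPM. EGR3 rose by 1.53 from 0.585 ± 0.137 to 1.69 ± 0.358 CPM. JUND and IER2, at 203 ± 10.5 and 43.7 ± 1.47 CPM in DMSO, did not pass (0.05 and 0.10). With GC content and length corrected 13 rose and the list's median was 0.374. Of 9 basement membrane and collagen genes, 7 rose and 0 fell, with a median of 0.53 and 0.262 with the correction (camera adjusted p = 6.68e-06, and adjusted p = 0.0227 with an estimated correlation); COL6A1 rose by 0.66, AGRN by 0.53 and FN1 by 0.53. With the correction 5 of these 9 rose, AGRN by 0.23, and COL18A1 (0.25, edgeR adjusted p = 0.135) and COL9A3 (0.12, 0.412) did not pass. Of 17 FOXO and KLF2 target genes, 5 rose and 1, TXNIP, fell; the list did not pass without the correction (median 0.04, camera adjusted p = 0.0923, and adjusted p = 0.151 with an estimated correlation) and passed with it (median 0.082, 0.0106), where TXNIP was left out for want of a GC value, so that these tests differ in their members. ITGB7 rose by 0.88, PIK3IP1 by 1.23 and BCL6 by 0.72. Single genes chosen after their values were seen were the endogenous retroviral gene ERVFRD-1, which rose from 2.65 ± 0.454 to 11.4 ± 0.371 CPM, EGR1, LGALS1 from 3.10 ± 0.219 to 7.31 ± 0.576 CPM, and TSC22D3 from 9.32 ± 0.920 to 18.2 ± 1.33 CPM.

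Of 31 proteasome subunits, 24 fell and 0 rose, with a median of -0.20 and -0.108 with the correction, where 13 fell (camera adjusted p = 6.05e-11, and adjusted p = 0.0827 with an estimated correlation). PSMA4 fell by 0.35 and PSMD1 by 0.30 (0.20 with the correction). Of 33 proteins of the spliceosomal snRNPs, 18 fell and 0 rose, with a median of -0.15 and -0.119 with the correction, where 16 fell (camera adjusted p = 3.57e-09, and adjusted p = 0.0827 with an estimated correlation). SNRPE fell by 0.47, LSM3 by 0.44 and SNRPG by 0.46, and with the correction SNRPE and SNRPG fell by 0.29 and 0.20.

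Whether the trend of fold changes with GC content and length makes the changes was weighed for lists and NOTCH receptors; the tests with the trend removed were chosen only after the result was seen, those with matched lists before. The nucleolar list kept a median of -0.219 with the trend removed. Without the correction it lay at percentile 0 of random lists matched on GC content, length and expression, whose medians lay mostly between -0.117 and -0.017. These therefore do not account for all of its fall. Matched lists are drawn gene by gene and lack the correlation among the list's own genes, estimated at 0.141, so percentile 0 overstates the certainty. The mitosis list had a median of -0.015 with the trend removed and lay at percentile 91.8 of the matched lists, so its fall may be no more than the trend. NOTCH3 kept 0.692, whereas NOTCH1 was left with 0.063, so the rise of NOTCH1 could be the trend. The trend itself could be technical or a response of the cells, and the counts cannot tell which.

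Lists of ribosome assembly, folding and nucleotide synthesis were lower by camera at its preset correlation although the MYC count was not (adjusted p = 0.110, 0.169 and 0.110 with an estimated correlation). The tests of the explanations below were chosen only after the result was seen. Cas9 cuts could leave frameshifted MYC transcripts that are still counted; the MYC log2 fold change of 0.092 allows this but cannot tell it from guides that did not act, and reads over the cut sites, not analysed here, would. Doxycycline itself slows mitochondrial translation, which might raise the integrated stress response. That list's median of 0.121 did not pass, and of its 16 tested genes 4 rose and 2 fell. With the correction the median was 0.066 (camera adjusted p = 0.364). Members that move both ways leave this explanation open. A doxycycline group without guides would be the test, and the series has none.

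All 8 tested nuclear copies of mitochondrial genes had negative log2 fold changes and 6 fell, with a median of -0.52, while mitochondrial genes held 0 counts. The largest falls, of MTND6P4 by 1.35 and MTND1P23 by 1.06, were at low levels. These copies were at 2.64 ± 1.27 and 2.34 ± 0.889 CPM in DMSO (SD, n = 3 each). The test on sequence identity was chosen only after the result was seen, that on the trend before. The copies' transcripts had a median identity of 98.3% to mitochondrial transcripts, so reads of mitochondrial RNA may have been counted on the copies. In that case the 8 copies are not separate observations. With the GC and length trend removed 4 fell and the median of all 8 was -0.324, so the trend does not account for all of the fall. No biological explanation was tested.

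The 6 samples can be split in 10 ways, too few to reach 5%, and the real split gave the highest value in each case, 1 of 10. It gave 4545 changed genes where the highest other was 0 by edgeR (159 to 569 genes at unadjusted p under 0.05 in the others, 6209 in the real one), 3310 with the correction where the highest other was 0 (at most 591 at unadjusted p under 0.05), and 19 lists by camera where the highest other was 15. Every other split mixes both treatments in each of its groups, so the treatment difference widens the spread within groups. The 0 calls there were thus close to fixed in advance and are no measure of chance. Part of the treatment difference also stays between those groups, so 15 lists is no chance level either. The other splits were not tested with another tool.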
